A study of Homo sapiens with 12 samples.

How the data were processed

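RNA-seq counts of 12 libraries from H1299 cells, 3 in each of 4 groups, were analysed. Per the labels, the cells carried stably integrated lentiviral hairpins, total RNA was extracted with TRIzol, and libraries were sequenced on an Illumina instrument. The authors deposited 3 tables, each setting a knockdown group beside the control, with raw counts per gene in whole numbers. Per the submitters' processing notes, FastQC, featureCounts and DESeq2 were used with the genome build GRCh37. The order of these steps, the aligner, the annotation, the versions and the use of strand are not given in the sources used here. Reads from overlapping, antisense or near-identical genes therefore cannot be told apart with certainty. The same tables hold the authors' deposited log2 fold changes, which are not on the scale of the values fitted here, and their adjusted p-values. Another 18 columns of normalised values were not used here.

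The lowest raw count in any table was 11, so low counts had been removed before deposit by a rule not given in the sources used here. The tables held 16919 genes for the α1 knockdown, 17801 for the α2 knockdown and 17370 for the double knockdown. The raw control counts were identical in the 3 tables. Tables were joined on the 16896 genes present in all of them. Columns named the group but carried no replicate number of the labels, so each library was assigned to its group only and is called here by its column number, S0 to S11. Gene names were those of the tables, in which 21 names had been turned into dates by a spreadsheet and were left as they stood. Of 17823 names, 14332 matched a current symbol, directly or through an older symbol. No coordinates are printed, because the reference used here for transcripts (GENCODE release 29, on GRCh38) is not on the build of the deposited tables.

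Totals over the joined genes ran from 24951408 to 34631481 counts per library. CPM, the count of a gene relative to the library total after scaling by TMM factors, was computed in edgeR with its standard multiplier. Changes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the raw counts, with a mean for each of the 4 groups and no covariate, so that all 12 libraries shared an estimate of the spread with 8 residual degrees of freedom. P-values were adjusted over all 16896 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The low-count filter of edgeR removed 0 genes. The common biological coefficient of variation was 2.37%. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Each knockdown was compared with the control, the knockdowns with each other, and an interaction term measured the departure of the double knockdown from the sum of the 2 single knockdowns on the log2 scale.

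A set of 42 gene lists was fixed before the data were examined, and the 38 lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 38 lists. The test was repeated with a correlation estimated for each list. The genes named were also fixed by rule beforehand. They are the AMPK subunit genes, the 6 largest increases and 6 largest decreases in each comparison with control, and the 3 largest each way in the other comparisons. These had to be called, to have an average log2 CPM of at least 2 and, except for the interaction, to lie apart from every library of the other group, and clone-named and antisense loci were skipped. Some genes that the rule selects are not reported here. Up to 4 called members were added for the 8 leading lists of a comparison, and up to 2 for other lists. REST, the members of the REST list and single cell-type markers were named after their values were seen. The counts per list given as "adjusted over the list alone" use an adjustment over that list's members only.

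The alternatives tried were the size factors of DESeq2, library totals without factors, the Wald test of DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 3 libraries, fits of only the 2 groups compared, stricter thresholds, other tests of gene lists, and leaving out each of the 12 libraries in turn. Comparisons that share the control libraries were set beside 20 simulations of unchanged groups. The edgeR step was tested on simulated data for the α1 comparison over 16896 genes, with 50 genes changed at each size. It recovered 26% of genes changed 1.1-fold, 60% at 1.2-fold, 82% at 1.5-fold and 96% at 2-fold, with 13 calls among the 16696 unchanged genes. In the same simulation design a cholesterol synthesis list lowered 1.2-fold was called, and 0 of the other lists were. Genes were drawn independently there, so this does not test false calls of lists whose genes move together.

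After the calls had been seen, heptamers in 3′ UTRs were tested. For 11902 protein-coding genes with a GENCODE 3′ UTR of at least 50 bases, log2 fold changes were limited to 1 in either direction and fitted on the length and GC content of the 3′ UTR. For each of 16384 heptamers, genes with and without it were compared by a z statistic, and 100 permutations of the genes gave the lowest value expected by chance. The search was limited to protein-coding genes after a first run over all genes with a 3′ UTR. In simulated fold changes 10 of 10 planted heptamers were recovered.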

Results

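Gene expression was measured by RNA-seq in H1299 cells, an established human lung carcinoma line, after delivery of short hairpin RNAs by lentivirus. The hairpins were aimed at PRKAA1 or PRKAA2, which encode the α1 and α2 catalytic subunits of AMP-activated protein kinase (AMPK), a kinase that restrains anabolic metabolism when cellular energy runs low. The 4 groups were a control given a hairpin without a target, an α1 knockdown, an α2 knockdown and a double knockdown, with 3 libraries each. Counts over the 16896 genes used totalled between 24951408 (library S11, double knockdown) and 34631481 (S4, α1 knockdown). The sources used here do not say whether libraries of a group came from separate cultures or transductions, so p-values measure only the spread between these libraries, which may be technical. All changes below were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and errors of log2 fold changes are SE from that fit.

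The targeted genes were examined first. PRKAA1 stood at 138 ± 1.28 CPM in the control (SD, n = 3), 33.1 ± 2.72 in the α1 knockdown, 136 ± 1.92 in the α2 knockdown and 30.35 ± 0.2997 in the double knockdown. The α1 knockdown thus kept 24.0% of the control level and the double knockdown 22.03%. PRKAA2 stood at 36.4 ± 0.902 CPM in the control, 37.6 ± 1.51 in the α1 knockdown, 14.98 ± 0.667 in the α2 knockdown and 29.9 ± 1.58 in the double knockdown, on 478 to 1261 counts per library. PRKAA2 therefore fell to 41.1% of control with the α2 hairpin alone but only to 82.1% in the double knockdown. The small fall in the double knockdown passed edgeR's quasi-likelihood test (log2 fold change -0.29 ± 0.04, Benjamini-Hochberg adjusted p = 1.86e-05), and PRKAA2 was also lower there than in the α1 knockdown (-0.33 ± 0.04, adjusted p = 0.00027). Among the other measured subunits, PRKAB2, which encodes the regulatory β2 subunit, rose in every knockdown, to 120% of control in the α1, 113% in the α2 and 119% in the double knockdown. PRKAG1, a γ subunit gene, rose in the double knockdown (0.11 ± 0.03), while PRKAB1 and PRKAG2 were not called in any comparison with control.

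**Figure D1:**
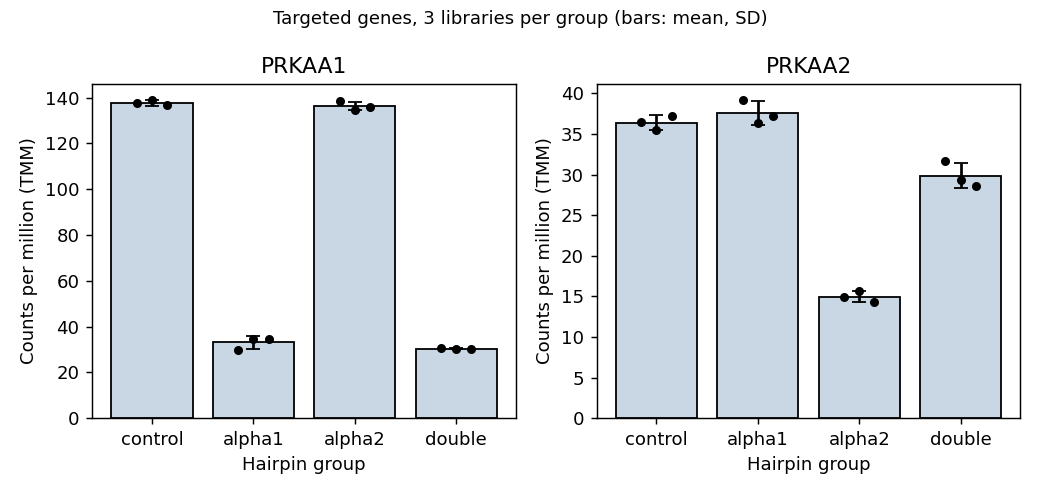
Expression in CPM (TMM) of PRKAA1 (left) and PRKAA2 (right) by hairpin group. Bars are means, error bars SD and points the 3 libraries of a group. PRKAA2 averaged 14.98 CPM in the α2 knockdown and 29.9 in the double knockdown, against 36.4 in the control.

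The comparison of the α1 knockdown with control asked which genes respond to loss of the α1 subunit. Genes of sterol synthesis fell together, and genes of the heat shock response and of the response to amino acid shortage rose. Among genes with an average log2 CPM of at least 2, the largest increases were in CCND2 (cyclin D2, log2 fold change 1.85 ± 0.11), SIRPA (a receptor for CD47, 1.31 ± 0.11), KIF21B (a kinesin, 1.26 ± 0.11), MYO1D (an unconventional myosin, 1.07 ± 0.11), GDPD5 (1.07 ± 0.10) and WNK2 (a kinase, 1.02 ± 0.13). After PRKAA1 itself, the large decreases included those of SHFM1 (-1.54 ± 0.04), NAP1L5 (-1.48 ± 0.07), SERINC3 (-1.11 ± 0.03) and TADA3 (a subunit of histone acetyltransferase complexes, -0.95 ± 0.03). The 3′ UTRs of NAP1L5, SERINC3 and TADA3 each contain the heptamer CTGCTTG, and that of SHFM1 was not searched. In all, 2130 genes rose and 2036 fell, but most changes were small. The median size among called genes was 0.18 on the log2 scale, and 32 genes rose and 16 fell by 2-fold or more.

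Of 24 measured genes of cholesterol synthesis, 20 fell and 1 rose in the α1 knockdown (21 and 1 adjusted over the list alone; camera adjusted p = 7.26e-14). They included FDFT1, which encodes squalene synthase (-0.38 ± 0.03), HMGCS1 (-0.34 ± 0.03), INSIG1, a sterol sensor partner (-0.47 ± 0.04), and DHCR7, the last step to cholesterol (-0.31 ± 0.03). Of 18 heat shock genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 8.44e-19), among them SERPINH1 (0.46 ± 0.03), HSPB1 (0.46 ± 0.03), HSPA1A (0.39 ± 0.03) and HSPA1B (0.38 ± 0.03). HSPA1A and HSPA1B are nearly identical in sequence, so their separate values are uncertain. Of 26 genes of the amino acid response, 21 rose and 2 fell (21 and 2 adjusted over the list alone; camera adjusted p = 1.58e-10), with ASNS, asparagine synthetase (0.26 ± 0.02), PSAT1 (0.25 ± 0.02) and PHGDH (0.32 ± 0.03) of serine synthesis, and ATF4, the transcription factor of this response (0.18 ± 0.02). These 3 lists were also called with an estimated correlation, with adjusted p of 0.000884 for cholesterol synthesis, 0.00224 for heat shock and 0.00122 for the amino acid response.

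Other lists of metabolic, histone and stress response genes were called in the α1 knockdown only at the preset correlation. Of 17 fatty acid synthesis genes, 9 fell and 1 rose, led by FASN (fatty acid synthase, -0.47 ± 0.03), SCD (stearoyl-CoA desaturase, -0.40 ± 0.02), FADS2 (-0.24 ± 0.04) and ACLY (ATP citrate lyase, -0.11 ± 0.02). That list had a camera adjusted p of 7.27e-05, and adjusted p = 0.134 with an estimated correlation. It was not called (camera adjusted p = 0.232) when the 4 members whose 3′ UTR contains CTGCTTG, FASN and SCD among them, were left out. Without such members the cholesterol synthesis, heat shock and amino acid response lists stayed called (camera adjusted p = 3.69e-10, 9.74e-18 and 3.69e-10). Of 13 mitochondrially encoded genes, 9 fell, including MT-ATP6 (-0.31 ± 0.02) and MT-CO3 (-0.24 ± 0.02), with adjusted p = 0.233 with an estimated correlation. Of 9 replication-dependent histone genes, 5 fell, including HIST1H1C (-0.48 ± 0.08) and HIST1H2BK (-0.28 ± 0.03), with adjusted p = 0.134 with an estimated correlation; histone genes are similar in sequence and their values are uncertain. Of 20 hypoxia response genes, 7 rose and 4 fell, with increases in DDIT4 (0.60 ± 0.05) and VEGFA (0.40 ± 0.03), and adjusted p = 0.0651 with an estimated correlation. Glycolysis genes (11 of 25 lower, 2 higher) and NF-κB and inflammatory genes (5 of 15 higher, 2 lower) had adjusted p of 0.225 and 0.114 with an estimated correlation. The list of 6 AMPK subunits was called at either correlation, but without PRKAA1 and PRKAA2 its other 4 genes had an unadjusted camera p of 0.154.

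The comparison of the α2 knockdown with control asked the same of the α2 subunit. Cholesterol synthesis genes fell and amino acid response genes rose here too, while class I antigen presentation and lysosomal genes rose. Among genes at that level of expression, the largest increases were in WNK2 (1.88 ± 0.11), TUBB4A (a β-tubulin, 1.76 ± 0.10), GDPD5 (1.71 ± 0.09), LITAF (1.48 ± 0.06), AIF1L (1.42 ± 0.10) and ARRB1 (β-arrestin 1, 1.29 ± 0.10). After PRKAA2 (-1.28 ± 0.05), the largest decreases at that level were in BCYRN1 (-0.85 ± 0.12), HABP4 (-0.82 ± 0.05), DYNC1LI2 (a dynein chain, -0.81 ± 0.03), GIT1 (-0.80 ± 0.04) and RTN1 (-0.75 ± 0.08). The 3′ UTRs of HABP4, DYNC1LI2 and GIT1 contain the heptamer GTCATGT, and that of RTN1 does not. BCYRN1 is a noncoding RNA with repeat-derived sequence, so its counts are uncertain. In all, 1693 genes rose and 1570 fell, of which 71 rose and 3 fell by 2-fold or more. With library totals as the only scaling, 2271 genes rose and 1128 fell, so that 66.8% of calls were increases, against 51.9% with TMM factors.

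In the α2 knockdown, 15 of 24 cholesterol synthesis genes fell and 0 rose (17 and 1 adjusted over the list alone; camera adjusted p = 3.87e-10), with HMGCS1 (-0.46 ± 0.03), LSS, lanosterol synthase (-0.25 ± 0.03), and FDFT1 (-0.24 ± 0.03). Of 26 amino acid response genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.98e-08), with ASNS (0.33 ± 0.02), GARS (0.19 ± 0.02), PHGDH (0.31 ± 0.03) and PSAT1 (0.18 ± 0.02). Of 14 antigen presentation genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 7.48e-10), among them HLA-B (0.60 ± 0.03), HLA-C (0.46 ± 0.03), HLA-E (0.26 ± 0.03) and HLA-F (0.90 ± 0.12), which resemble each other in sequence. Of 36 lysosomal and TFEB target genes, 16 rose and 1 fell (21 and 2 adjusted over the list alone; camera adjusted p = 7.66e-06), with LAMP1 (0.26 ± 0.02), CTSL (cathepsin L, 0.21 ± 0.03), ATP6V0E1 (0.20 ± 0.03) and TPP1 (0.18 ± 0.03). Among 15 NF-κB and inflammatory genes 5 fell and 1 rose (camera adjusted p = 0.000631), with BIRC3 (-0.53 ± 0.03), PLAU (-0.30 ± 0.02), IER3 (-0.20 ± 0.04) and SOD2 (-0.11 ± 0.02). With an estimated correlation these 5 lists kept adjusted p of 0.00279, 0.00313, 0.0161, 0.0288 and 0.0318, in the order given.

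The remaining calls among the α2 lists did not hold with an estimated correlation, apart from the AMPK subunits, whose 4 genes other than the targets had an unadjusted camera p of 0.570. Of 13 mitochondrially encoded genes, 11 fell and 1 rose, with MT-CO1 (-0.28 ± 0.02) and MT-ND4 (-0.20 ± 0.02), and adjusted p = 0.0998 with an estimated correlation. Of 25 glycolysis genes, 12 fell and 3 rose, with GAPDH (-0.22 ± 0.02) and LDHA (-0.20 ± 0.02), and adjusted p = 0.0978 with an estimated correlation. Fatty acid synthesis genes (7 of 17 lower, 3 higher) included SCD (-0.33 ± 0.02) and FASN (-0.30 ± 0.03), with adjusted p = 0.253 with an estimated correlation. At the preset correlation that list stayed called without its members whose 3′ UTR contains GTCATGT (camera adjusted p = 0.0103). Interferon-stimulated genes (6 of 25 higher, 1 lower) included OAS3 (0.51 ± 0.05), with adjusted p = 0.0825 with an estimated correlation. Cytosolic ribosomal protein genes (13 of 51 lower), MYC and ribosome biogenesis genes (9 of 28 lower), G1/S genes (9 of 35 lower, 1 higher), TGF-β targets (6 of 23 lower, 2 higher) and immediate early genes (4 of 23 higher) had adjusted p of 0.657, 0.0978, 0.0978, 0.0978 and 0.291 with an estimated correlation. The heat shock list was not called in the α2 knockdown (4 of 18 higher, 2 lower; camera adjusted p = 0.183), although HSPB1 (0.62 ± 0.03) and SERPINH1 (0.47 ± 0.03) rose.

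The comparison of the double knockdown with control asked what happens when both hairpins are present. Heat shock and amino acid response genes rose and cholesterol synthesis genes fell, and PRKAA2 remained at 82.1% of control in these cells. Among genes at that level of expression, the largest increases were in CCND2 (1.57 ± 0.11), SIRPA (1.56 ± 0.11), KIF21B (1.44 ± 0.11), GDPD5 (1.36 ± 0.10), FAM43A (1.28 ± 0.09) and ARRB1 (1.24 ± 0.10). After PRKAA1 (-2.18 ± 0.04), the large decreases included those of NAP1L5 (-1.63 ± 0.07), SHFM1 (-1.51 ± 0.04), SERINC3 (-1.09 ± 0.03) and TSHZ3 (-1.09 ± 0.12). In all, 2797 genes rose and 2721 fell, of which 55 rose and 23 fell by 2-fold or more. Library S9 differed from the other double knockdown libraries beyond counting noise, and without it 3264 genes rose and 3322 fell. The joint fit pools its spread over all 12 libraries, so these calls rest partly on less variable groups and may be too many. At the same threshold the authors' deposited table called 1494 genes higher and 1485 lower here, fewer than in the α1 knockdown (1684 and 1680). Whether the double knockdown changed more genes than the α1 knockdown thus depends on the fit.

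In the double knockdown, 13 of 18 heat shock genes rose and 0 fell (15 and 2 adjusted over the list alone; camera adjusted p = 2.49e-25), with SERPINH1 (0.61 ± 0.03), HSPA1A (0.54 ± 0.03), HSPA1B (0.53 ± 0.03) and HSPB1 (0.59 ± 0.03). Of 24 cholesterol synthesis genes, 20 fell and 2 rose (21 and 2 adjusted over the list alone; camera adjusted p = 1.01e-11), with HMGCS1 (-0.51 ± 0.03), FDFT1 (-0.42 ± 0.03), INSIG1 (-0.53 ± 0.04) and DHCR7 (-0.27 ± 0.03). Of 26 amino acid response genes, 20 rose and 1 fell (22 and 2 adjusted over the list alone; camera adjusted p = 1.01e-11), with PHGDH (0.42 ± 0.03), PSAT1 (0.26 ± 0.02), ATF4 (0.27 ± 0.02) and ASNS (0.26 ± 0.02). With an estimated correlation the adjusted p was 0.00129 for heat shock and 0.000828 for each of the other 2 lists. The fatty acid synthesis list (10 of 17 lower, 2 higher) included SCD (-0.51 ± 0.02), FASN (-0.52 ± 0.03), FADS1 (-0.24 ± 0.03) and LPIN1 (-0.20 ± 0.03), with adjusted p = 0.121 with an estimated correlation, and was not called without the members whose 3′ UTR contains either heptamer (camera adjusted p = 0.383). Histone genes (6 of 9 lower), NF-κB and inflammatory genes (7 of 15 higher, 1 lower) and antigen presentation genes (6 of 14 higher, 1 lower) had adjusted p of 0.127, 0.0937 and 0.202 with an estimated correlation. Library S9 stood apart from S10 and S11 in the histone list (median log2 difference -0.21) and the small RNA machinery list (0.14). From the mean of the α1 libraries S9 differed less, by -0.10 and 0.01. These values do not show whether S9 or the pair S10 and S11 is the exception. Among the NF-κB genes, ICAM1 (0.80 ± 0.09), BIRC3 (0.43 ± 0.03), NFKB2 (0.40 ± 0.03) and NFKBIA (0.32 ± 0.05) rose. Immediate early genes (12 of 23 higher, 4 lower), hypoxia genes (8 of 20 higher, 5 lower), apoptosis regulators (7 of 27 higher, 2 lower) and small RNA machinery genes (7 of 15 lower, 1 higher) had adjusted p of 0.204, 0.108, 0.121 and 0.596 with an estimated correlation. The last of these lists included DICER1 (-0.52 ± 0.04) and AGO1 (-0.20 ± 0.04), of the pathway that processes and loads small RNAs, and was not called without its heptamer members (camera adjusted p = 0.727). The AMPK subunit list was called, and its 4 genes other than the targets had an unadjusted camera p of 0.149.

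**Figure D2:**
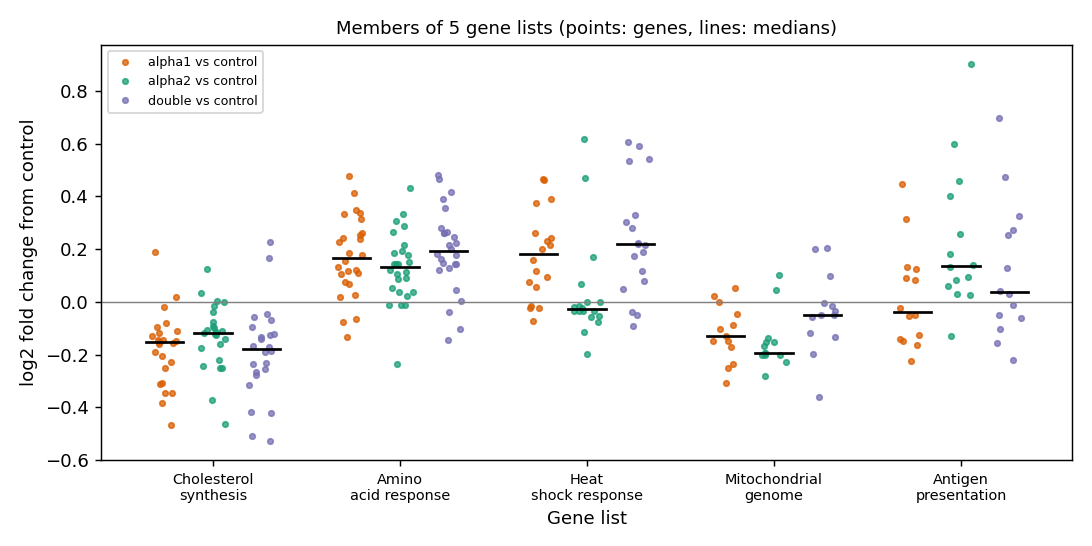
Log2 fold change from control (vertical axis) of the members of 5 gene lists in the 3 knockdowns. Points are genes and black lines are medians. The median of the heat shock list was 0.18 in the α1 knockdown, -0.03 in the α2 knockdown and 0.22 in the double knockdown, and cholesterol synthesis lay below 0 in all 3.

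The overlap of the knockdowns was examined next. The α1 and α2 knockdowns shared 719 genes called higher in both and 545 called lower in both, against 213 and 189 for independent lists, and 241 genes were called in opposite directions. The α1 and double knockdowns shared 3166 genes called in the same direction and 3 in opposite directions, and the α2 and double knockdowns shared 1532 and 236. In all 3 knockdowns 651 genes were called higher and 455 lower. Since the comparisons share control libraries, unchanged groups were simulated against the same controls. The simulations gave on average 0.05, 0 and 0.1 shared calls for these 3 pairs, and a covariance of log2 fold changes across genes of 0.00479, 0.00479 and 0.00481. The simulated groups had no changed genes and hence few calls. Their shared counts therefore do not show how many of the observed shared calls the common controls added. The observed covariances were 0.0175, 0.0344 and 0.0225. The correlation across genes was 0.476, 0.819 and 0.525, against simulated means of 0.503, 0.485 and 0.498, and genes are not independent replicates. The 3 controls could not be split into sets of at least 2, so part of the excess may come from the shared controls. Without library S9, 1915 genes were shared in the same direction by the α1 and α2 knockdowns. S9 is in neither of these groups nor the control, so leaving it out acts only through the spread and scaling of the joint fit.

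The α1 and α2 knockdowns were also compared with each other. Heat shock genes and NF-κB genes were higher in the α1 knockdown. Of 18 heat shock genes, 12 were higher and 1 lower there (camera adjusted p = 6.02e-11, and adjusted p = 0.0244 with an estimated correlation), and of 15 NF-κB and inflammatory genes 9 were higher and 1 lower (9.02e-08, and adjusted p = 0.00928 with an estimated correlation). Histone genes (7 of 9 lower in the α1 knockdown), antigen presentation genes (8 of 14 lower), lysosomal genes (15 of 36 lower, 1 higher) and interferon-stimulated genes (11 of 25 lower, 4 higher) had adjusted p of 0.0744, 0.0744, 0.0872 and 0.0869 with an estimated correlation. Besides the targets, CCND2 (1.18 ± 0.10) and MYPN (1.13 ± 0.08) were, at that level of expression, the genes most raised in the α1 relative to the α2 knockdown, and TUBB4A (-1.55 ± 0.10) and SHFM1 (-1.50 ± 0.04) the most lowered. The direct test called 2309 genes higher and 2320 lower in the α1 knockdown.

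The double knockdown was then set against each single knockdown. Against the α1 knockdown edgeR called 324 genes higher and 243 lower, none of them by 2-fold or more. With no fold required, edgeR gave 3369 genes at an unadjusted p under 0.05, and DESeq2 called 367. The largest differences at an average log2 CPM of at least 2 were in FAM98B (-0.49 ± 0.05), MT2P1 (-0.52 ± 0.13), ZNF793 (-0.50 ± 0.10), B4GALNT4 (0.45 ± 0.10), SERPINB7 (0.42 ± 0.07) and OAF (0.41 ± 0.08). MT2P1 is a metallothionein pseudogene and shares sequence with its parent genes. Some of these calls were lost under alternatives: MT2P1 without S3, S4, S10 or S11, B4GALNT4 without S4, S5 or S10, OAF without S4, and all 4 of MT2P1, B4GALNT4, OAF and ZNF793 when only the 2 groups were fitted (highest adjusted p over all alternatives 0.207, 0.0724, 0.0712 and 0.0747 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The fold changes of this comparison followed transcript length (Spearman rho -0.463 over 8296 coding genes), more than those of the α1 (0.0958), α2 (0.0532) and double knockdown (-0.165) against control, so part of the calls may reflect a difference between libraries. In this comparison 12 lists were called, of which 0 held with an estimated correlation. The count depended on single libraries: it was 3192 without S9, 119 without S4, 130 without S11, 160 without S10, 183 without S3 and 210 without S5, and 20 when only the 2 groups were fitted. Against the α2 knockdown 2703 genes were higher and 2670 lower, among them MYPN (1.18 ± 0.08), TGFB2 (1.05 ± 0.10) and PRKAA2 (0.996 ± 0.05) raised most at that level and PRKAA1 (-2.17 ± 0.04) and SHFM1 (-1.47 ± 0.04) strongly lowered. Heat shock genes (15 of 18 higher; adjusted p = 0.00519 with an estimated correlation) and MYC and ribosome biogenesis genes (16 of 28 higher, 2 lower; adjusted p = 0.0409) were among the 9 lists called there, of which 5 were also called with an estimated correlation.

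The interaction term asked whether the double knockdown departed from the sum of the single knockdowns on the log2 scale. Since PRKAA2 was at 82.1% of control in the double knockdown and at 41.1% in the α2 knockdown, the term does not compare equal losses of α2. PRKAA2 itself had an interaction of 0.95 ± 0.06. Apart from it, RN7SL1 (0.77 ± 0.20) and BCYRN1 (0.77 ± 0.17), which are noncoding RNAs with many copies or repeats in the genome, were the highest at that level of expression, and WNK2 (-1.89 ± 0.16), PTPRS (-1.51 ± 0.14) and TUBB4A (-1.46 ± 0.16) the lowest. The cholesterol synthesis list was positive (11 of 24 higher; camera adjusted p = 6.08e-08, and adjusted p = 0.0076 with an estimated correlation), and the amino acid response list was negative (9 of 26 lower, 1 higher; 0.000151, and adjusted p = 0.0149 with an estimated correlation). A change common to every knockdown against the shared control enters this term with its sign reversed. These lists fell and rose, respectively, in every knockdown, so an offset of the control libraries would give the same signs and cannot be told apart. In all, 1622 genes were called, and 3708 without library S9. RN7SL1 was not called without S0, S4, S5 or S7 (highest adjusted p 0.07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The interaction also followed transcript length (Spearman rho -0.342 over 8296 coding genes).

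Library-level differences were measured alongside. On principal component PC3, which held 9.65% of the variance, S9 lay at -8.84, the other double knockdown libraries at 10.3 and 11.4, and the α1 libraries between -6.51 and -5.93. Pairs of libraries within the other groups had a chi-square of 1.21 to 1.46 per degree of freedom over genes, as had S10 and S11 (1.44), while S9 had 6.38 against S10 and 4.30 against S11. Mitochondrial ribosomal RNA made up 0.147 to 0.151% of counts in control libraries, 0.181% in α1 libraries, 0.155 to 0.167% in α2 libraries and 0.200 to 0.209% in double knockdown libraries. Of 16 blood cell markers 0 were in the joined tables, and 4 of 12 fibroblast markers summed to 33.6 ± 0.591 CPM in the control and 30.4 ± 0.427, 33.5 ± 1.33 and 30.3 ± 0.915 in the α1, α2 and double knockdowns (SD, n = 3). Endothelial markers (4 of 11 measured) summed to 19.8 ± 0.759 CPM in the control and 24.5 ± 0.920, 23.4 ± 1.65 and 24.8 ± 0.569 in the knockdowns in that order. Alveolar and airway markers (2 of 15) summed to 5.48 ± 0.119 CPM in the control and 5.12 ± 0.218, 4.45 ± 0.139 and 4.96 ± 0.812 in the knockdowns, and neuroendocrine markers (6 of 16) to 578 ± 2.80 and 588 ± 4.30, 548 ± 5.92 and 588 ± 19.6. These sums were dominated by UCHL1 (481 of the neuroendocrine CPM in the control) and PRRX1 (26.5 of the fibroblast CPM), and other members, named after their values were seen, moved apart from them. COL1A1 rose in each knockdown (0.78 ± 0.16, 1.66 ± 0.14 and 0.96 ± 0.16), CHGB (0.87 ± 0.10) and SYP (0.77 ± 0.15) rose in the α2 knockdown, and MFAP5 fell in the α1 (-2.01 ± 0.18) and double knockdowns (-1.62 ± 0.17).

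**Figure D3:**
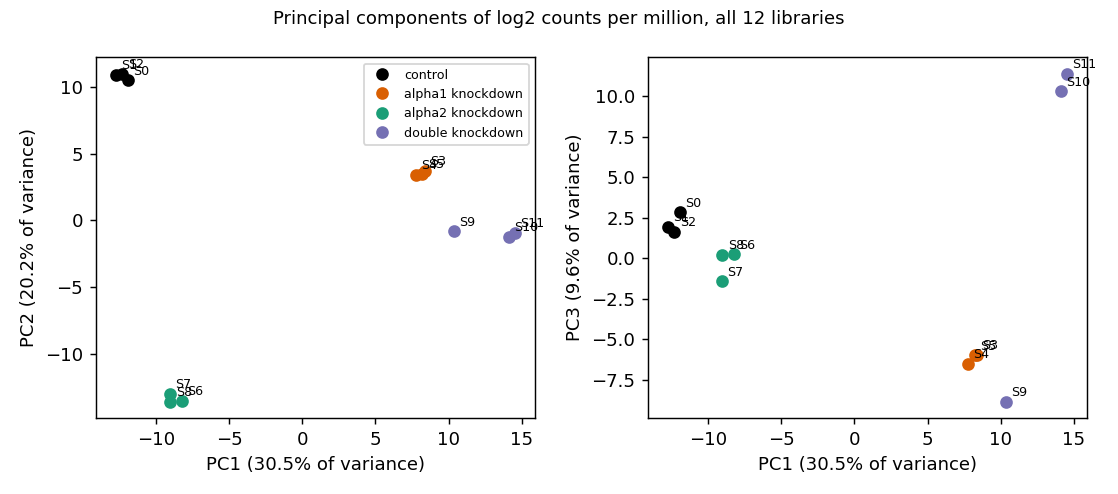
Principal components of log2 CPM for all 12 libraries, with PC1 (30.5% of variance) against PC2 (20.2%) on the left and against PC3 (9.65%) on the right. Colours are groups and labels are library numbers. S9 lies at -8.84 on PC3 and the other double knockdown libraries at 10.3 and 11.4.

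The authors' deposited table for each knockdown listed adjusted p-values of their own. At a value under 0.05, the authors' deposited table called 1684 genes higher and 1680 lower in the α1 knockdown, 1444 and 1284 in the α2 knockdown, and 1494 and 1485 in the double knockdown. Of the genes tested here, 3177, 2495 and 2967 were called in both the authors' deposited table and the present fit, and these had the same direction without exception.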

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

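The tests of library labels, of length among more expressed genes and of length as the whole of the S9 difference were chosen after the result was seen. The results in the next paragraph were singled out because a direct test of the difference between hairpins, or of the interaction, called them. List counts are at the preset correlation unless said otherwise.

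The α1 and α2 knockdowns differed in 4629 genes and 7 gene lists by edgeR's quasi-likelihood test and camera, of which 2 lists were also called with an estimated correlation. Among genes with an average log2 CPM of at least 2, the largest differences were in PRKAA2 (log2 1.32), CCND2 (1.18) and MYPN (1.13) on the higher side, and PRKAA1 (-2.04), TUBB4A (-1.55) and SHFM1 (-1.50) on the lower side. The interaction term called 1622 genes (3708 without library S9) and 11 lists, of which 8 were also called with an estimated correlation. At that level of expression PRKAA2 (0.95), RN7SL1 (0.77) and BCYRN1 (0.77) were highest and WNK2 (-1.89), PTPRS (-1.51) and TUBB4A (-1.46) lowest.

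The libraries were also split in other ways. For the comparisons of 3 against 3 libraries, 1 of 10 splits, the real split, gave as many genes, and 10 splits are too few for a share under 0.05. The other splits put libraries of both groups on each side, so differences between the groups enter the spread and lower the calls beforehand. Low counts from them therefore say nothing about chance. The real and highest other counts were 4166 and 0 for the α1 knockdown, 3263 and 0 for the α2 knockdown, 5518 and 0 for the double knockdown, 4629 and 0 for α1 against α2, and 5373 and 0 for double against α2. For double against α1 they were 567 and 424, the latter with S9 grouped with S4 and S5, which points to a structure that sets S9 apart from S10 and S11. For the lists of the α1, α2 and double knockdowns, 1 of 10 splits gave as many, and the real and highest other counts were 10 and 5, 15 and 6, and 12 and 7. For the interaction 1 of 100 splits gave as many genes, with 152 as the highest other count, but these splits mix the large differences between groups into the spread and say nothing about the interaction itself.

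The double knockdown libraries lay close to the α1 libraries, and S9 lay apart from S10 and S11. Against mislabelled α1 libraries, PRKAA2 was lower in the double knockdown by a log2 difference of -0.3278, and in S9 alone it stood at 31.67 CPM, below the α1 libraries (36.3 to 39.2). A weaker α2 knockdown in the double cells may account for the closeness: over 3262 genes called in the α2 knockdown, the difference of double from α1 followed the α2 effect with a slope of 0.1446 (95% interval 0.128 to 0.160 from a bootstrap of genes), and PRKAA2 itself showed 0.258 of its α2 effect. Genes are not independent replicates, so this interval and those of single libraries below leave out the spread between libraries. A still weaker α2 knockdown in S9 stays open: its slope (0.151) lay between those of S10 (0.153) and S11 (0.130), 0.0217 above the lower with overlapping intervals, but PRKAA2 itself showed 0.192 of its α2 effect in S9, against 0.278 and 0.305. Transcript length may explain part of the S9 difference, with a Spearman rho of 0.488 over 12195 coding genes, between the bounds of 0.3 and 0.5 set beforehand, and 0.656 over the 8296 more expressed. Correction for length and GC content left an SD of 0.07897 (from 0.107), above every library of the other groups (at most 0.0541), so these measures did not account for the whole. They come from a chosen GENCODE transcript of each gene, which may not be the transcript expressed. The remaining SD therefore cannot exclude length as the whole.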

How the results depend on the processing

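The alternative without heptamer genes was chosen after the result was seen. Of 325 alternatives for 16 counts, 282 stayed within 1.5 times, and 43 did not; the cause was not tested. For 336 results on named genes, 6010 of 6036 alternatives left the call as it was, 19 ended it, 7 gave a call, and 0 reversed it.

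At an adjusted p under 0.01, 1308 genes were higher and 1263 lower in the α1 knockdown, 1069 and 897 in the α2 knockdown, with 2928 for α1 against α2, 122 for double against α1, 3548 for double against α2, 775 for the interaction, and overlaps of 672 (α1 and α2), 2023 (α1 and double) and 882 (α2 and double). With a 2-fold change also required at an adjusted p under 0.05, the counts were 32 and 16, 71 and 3, and 55 and 23 for the α1, α2 and double knockdowns. They were then 38, 0, 37 and 58, with overlaps of 19, 40 and 33, in the same order. For double against α1, the comparison with 0, edgeR gave 3369 genes at an unadjusted p under 0.05 when no fold was required. DESeq2 called 1007 genes lower in the α2 knockdown, 367 for double against α1, 1016 for the interaction, and an overlap of 808 for α1 and α2; it gave no adjusted p for 9500 genes in double against α1. A fit of only the 2 groups called 20 genes for double against α1. An estimated correlation left 4, 6 and 4 lists in the α1, α2 and double knockdowns, and fry called 18, 27 and 25.

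Leaving out each library in turn gave 1624 to 2782 genes higher and 1535 to 2720 lower in the α1 knockdown, 1295 to 2318 and 1102 to 2253 in the α2 knockdown, and 2239 to 3264 and 2275 to 3322 in the double knockdown. It gave 3549 to 5816 for α1 against α2, 119 to 3192 for double against α1, 4288 to 6513 for double against α2, 1150 to 3708 for the interaction, and overlaps of 904 to 1915, 2555 to 3733 and 1157 to 2070. Lists ranged over 10 to 11, 14 to 17 and 10 to 14. Without S9, counts moved by over 1.5 times for double against α1 (3192), the interaction (3708) and the overlap of α1 and α2 (1915); for double against α1 they also did without S3 (183), S4 (119), S5 (210), S10 (160) and S11 (130). Without heptamer genes, 1607, 1285 and 2004 genes were lower in the α1, α2 and double knockdowns. CTGCTTG is present in 15.1% and GTCATGT in 9.79% of all genes with a searched 3′ UTR, so leaving such genes out lowers the counts in any case. No paired analysis was possible because the columns carry no replicate numbers, so the replicate block was not run.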

Other observations

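The tests of whether genes lowered by the α1 hairpin also fell with the α2 hairpin, and of genes near the risers in GC content, were chosen after the result was seen, and the 3′ UTR of REST was searched after the change of REST was seen. The heptamer and REST tests were planned after the calls, before their own results.

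Abundant genes fell with each hairpin, and their 3′ UTRs shared a heptamer particular to that hairpin. CTGCTTG had the lowest statistic in the α1 knockdown (-10.32, lowest of 100 permutations -4.78) and in the double knockdown (-8.91), but ranked 14901 from the lowest in the α2 knockdown, where GTCATGT was lowest (-12.07, lowest permuted -4.79) and ranked 9032 in the α1 knockdown; in the double knockdown GTCATGT ranked only 285 (-2.41), and against the α1 knockdown it reached -4.91, not past the lowest permuted -5.29. Seed matches, that is off-target pairing of the hairpins with 3′ UTRs, may therefore underlie part of the falls. CTGCTTG was present in 54.2% of the 48 coding genes that fell by 0.5 or more with the α1 hairpin and in 13.7% of genes not called, and GTCATGT in 57.6% of 33 and 8.77%. Both heptamers were picked from these same fold changes, so these shares describe the falls and are no separate support. CTGCTTG occurs in the PRKAA1 transcript 1 time (0.311 expected by chance), as it also does in the PRKAA2 transcript, and GTCATGT in the PRKAA2 transcript 2 times (0.571 expected), a weak test, and the hairpin sequences are not given in the sources used here. An effect shared by loss of either subunit stays open as well: genes that fell with the α1 hairpin, picked without 1 control library and measured in the α2 knockdown against that library, had medians of -0.07018, -0.0756 and -0.0994, the last at the bound of -0.1, with -0.11, -0.14 and -0.16 among those without CTGCTTG and -0.04, -0.06 and -0.04 among those with it.

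In the α2 knockdown 71 genes rose by 2-fold or more, and relief from the repressor REST is a candidate explanation for part of them. Of 47 REST targets listed before the test, 17 were measured, and 10 rose and 1 fell (camera p = 0.00217 with an estimated correlation), among them APLP1 (0.52), INA (0.47) and DISP2 (0.52). The REST list was drawn up after the calls. CHGB and SYP, among its rises, also belong to the neuroendocrine list, so it is not fully independent of the calls. REST itself fell in the α2 knockdown (log2 fold change -0.20, adjusted p = 0.000521 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and its 3′ UTR contains GTCATGT, so that the fall may be a seed match rather than an effect of α2 loss. Against REST as the only reason, INA, SCN3B and SRRM3 rose in all 3 knockdowns (SCN3B 0.91, 1.27 and 1.28 in the α1, α2 and double knockdowns), although REST was not called lower in the α1 or double knockdown, and SCN3B and SRRM3 were the only measured targets to rise 2-fold with the α2 hairpin. GC content may contribute, since the 69 coding risers had a median GC content of 59.2% (48.4% in all coding genes), fold changes of 3899 less expressed genes followed it (Spearman rho 0.232), and GGCCCCC led 19 heptamers of raised genes. The 20 genes nearest to each riser in GC content, length and expression had medians of at most 0.4242 (typically 0.12), against 1.24 for the risers. A bias that acts alike on genes of like overall GC content and length thus did not account for the whole. Risers were picked by their size and neighbours were not, so a GC bias that differs between such genes is not excluded. A correction over all coding genes hardly moved any gene (1.219 after it) and decided nothing.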
